A study of Mus musculus with 12 samples.

How the data were processed

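Total RNA from mouse liver was measured on 12 single-colour oligonucleotide arrays (Phalanx Mouse OneArray, version 2, release 2.1). The arrays came from 6 liver samples in 3 groups, an untreated control, mice made diabetic with STZ (streptozotocin, a toxin of insulin-producing beta cells) and STZ mice given MENS, with 2 samples per group and 2 arrays per sample. MENS is not spelled out in the labels and is used here as the name of the treatment. Per the labels' protocols, it was given with a printed circuit board driven by a MENS device for 1 h per day on 5 days per week over 6 weeks. RNA was extracted with TRIzol, checked for integrity and absorbance, amplified to amino allyl aRNA and labelled with Cy5, per the labels' protocols. The labels do not say that each sample is 1 animal, so p-values measure only the spread between these samples.

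The deposited values are linear probe intensities on which the authors had already acted before deposit. Sorted values were nearly the same on every array: leaving out the 1000 lowest of each array, they spanned at most 6.3% of their mean, which is the form quantile normalization leaves. Array medians lay between 768.89 and 770.33, and between 44 and 52 of the 26423 probes per array were below 0, with a lowest value of -73.94, the form background subtraction leaves. The background and normalization methods are not given in the sources used here. limma 3.30.7 is named per the submitters' processing notes, without its role.

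The deposited normalization was kept. Values below 0 were set to 0, an offset of 50 was added and log2 was taken, so differences are on the log2(intensity + 50) scale and understate changes of dim genes. The mean intensity of 652 genes (3.7%) was under 50. The number of arrays limits the precision. Probes were named from the platform annotation. Of the 26423 probes, 20377 had 1 gene symbol, 0 had several and 6046 were unnamed here. Symbols were updated through a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. Of the named probes, 18213 carried a current symbol, 2126 were matched by a synonym and 38 kept the platform's name. The brightest probe stood for each of the 17742 genes, which decided between probes for 2278 genes.

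The 2 arrays of a sample were averaged, and 1 model with a mean per group was fitted to the 6 samples with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, leaving 3 residual degrees of freedom and adding 3.2 prior degrees of freedom. Values were read in with the R package data.table (version 1.17.8), and plots were drawn with Python 3.11.15. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. An exact permutation test of 2 against 2 samples cannot give a p below 0.33 and was not used. Errors of log2 differences are standard errors from the limma model, and errors of group means are SDs.

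Lists of genes (36, covering liver pathways and markers of other cell types) were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Adjustment was over the 36 lists of a comparison. Camera asks whether a list moves relative to other genes, fry whether its genes move on balance 1 way. Members were also counted with p adjusted over the list alone. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. By the naming rule, up to 8 genes per direction were named per comparison among those past the threshold whose samples did not overlap. Missing places were filled with the genes of smallest unadjusted p without overlap, skipping predicted genes and clones. A panel of 16 metabolic genes was also named whatever the result, of which 11 were measured, and the others are not reported here. No list member passed over all genes, so list examples, including those that did not pass, were chosen after their values were seen, mostly by smallest p.

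Comparisons that share samples were set beside 100 simulations of unchanged groups, with each gene drawn independently. The gene test was also run on simulated data with 17742 genes, of which 50 were changed in the STZ group at each of 4 sizes. For STZ against control it recovered 20%, 92%, 96% and 98% of genes changed by 1, 2, 3 and 4 on the log2 scale, with 6 unchanged genes called. For STZ+MENS against STZ it recovered 22%, 92%, 96% and 98%, with 12 unchanged genes called. For STZ+MENS against control, where no gene was changed, 0 were called. These rates depend on how many genes were changed and by how much, because the adjusted threshold moves with them. They do not give the recovery in the measured data, where Mt2 differed by 4.56 ± 0.42 between STZ and control and was not called. A simulated list shifted by 0.5 in the STZ group had an adjusted p of 3.38e-10 against control with the preset correlation and 0.327 with the estimated one. For STZ+MENS against STZ these were 1.49e-07 and 0.494. In 100 runs of an unshifted list of 16 genes whose members were correlated at 0.3, p was under 0.05 in 39% with the preset and 5% with the estimated correlation, for STZ against control. The preset test is thus liberal where members vary together, and the estimated one missed a shifted list. With an estimated correlation, camera takes p from the 3 residual degrees of freedom. With a preset one, it takes p from degrees of freedom set by the number of genes.

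Alternatives covered normalization, dim probes, the choice of probe, the variance model, weights, the groups in the fit, the handling of arrays, replicate blocks, each sample left out and thresholds. Offsets of 16 and 200, leaving out genes with discordant arrays, and covariances with no sample in common were added after seeing the data. The main offset of 50 was not fixed beforehand either. Groups of 2 are too small to count other splits of the samples or to look for a stray sample within a group. All columns of the deposited table were used.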

Results

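Liver gene expression was compared between untreated control mice, STZ mice and STZ mice that received MENS. The labels give an age of 8 weeks without saying whether at the start or at sampling. Each group held 2 samples, called sample 1 and sample 2, and each sample was measured on 2 arrays, so n = 2 per group in all that follows. Expression is given as log2 intensity with the offset described for the processing, for 17742 genes.

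Arrays of the same sample correlated across genes at 0.986 to 0.996, arrays of different samples of a group at 0.976 to 0.988 and arrays of different groups at 0.958 to 0.985. These correlations are across genes, which are not independent replicates. Pooled over all samples or groups for each gene, the SD had a median of 0.136 between arrays of a sample and 0.173 between samples of a group. Taken within each group without pooling, the median SD between samples was 0.127 in control, 0.122 in STZ and 0.152 in STZ+MENS. The first principal component held 32.5% of the variance and the second 20.7%. The control samples scored 33.5 and 28.5 on the second component, and the other 4 samples lay between -23 and -6.5. On the first component STZ scored -38.9 and -25, the controls -3.6 and 4.3, and STZ+MENS 50.2 and 13.1, so on this component the STZ+MENS samples lay furthest apart within a group.

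**Figure D1:**
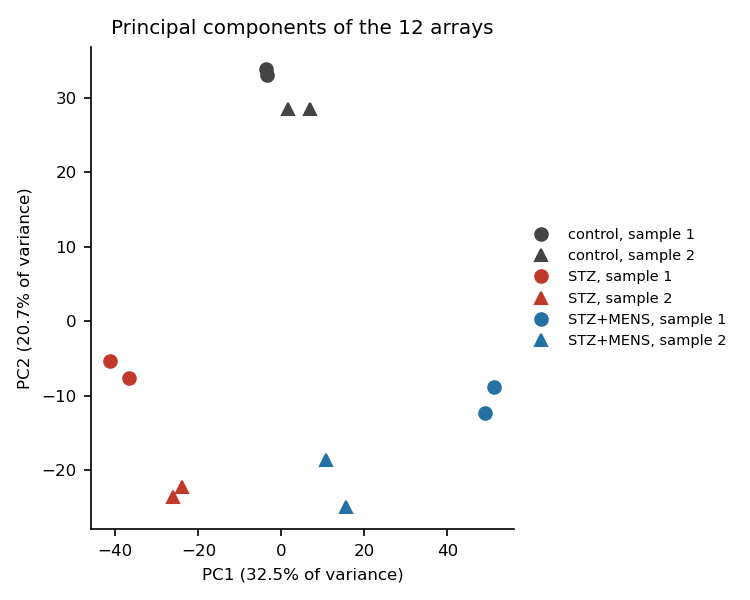
Scores of the 12 arrays of the 6 liver samples on the first (32.5%) and second (20.7%) principal components of log2 intensity, each point an array. The controls stand apart on the second component, and STZ+MENS sample 1 (50.2, averaged over its arrays) lies further out on the first than sample 2 (13.1).

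The first comparison asked how livers of STZ mice differed from control livers. Genes of cholesterol synthesis were lower in STZ: 11 of 16 measured members fell with p adjusted over the list alone, 0 rose and 5 did not pass. Mvd, the mevalonate decarboxylase of the pathway, was 8.26-fold lower (log2 -3.05 ± 0.33 SE), with log2 levels of 13.90 ± 0.37 (SD) in control and 10.85 ± 0.26 in STZ. Sqle, squalene epoxidase, differed by -2.21 ± 0.34, and Insig1, a sterol-responsive regulator, by -1.63 ± 0.20. The list was called lower by camera (adjusted p = 5.69e-11, median log2 -1.13), with adjusted p = 0.295 with an estimated correlation. Genes of fatty acid synthesis were lower as well: 9 of 16 fell and 1, Acss2 (0.45 ± 0.16), rose with p adjusted over the list alone. Scd1, the stearoyl-CoA desaturase, went from 19.12 ± 0.02 (SD) to 16.05 ± 0.92. It was the brightest probe on 3 of the 4 control arrays and ranked 2 on the other, where the deposited normalization fixes the value, so its control SD understates the spread and its log2 difference of -3.07 ± 0.76 is limited by the top of the scale. Acaca, which makes malonyl-CoA, differed by -1.50 ± 0.22, Thrsp, a lipogenic regulator, by -2.12 ± 0.35, and Fasn, fatty acid synthase, by -2.69 ± 0.72. The camera adjusted p was 0.000646, and adjusted p = 0.542 with an estimated correlation. In neither list did a member pass over all genes tested (0 and 0).

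Genes of fatty acid oxidation and PPARalpha targets were higher in STZ: 10 of 20 rose and 0 fell with p adjusted over the list alone (camera adjusted p = 5.18e-05; adjusted p = 0.295 with an estimated correlation). The acyl-CoA thioesterases Acot1 and Acot2 differed by 2.40 ± 0.22 and 1.71 ± 0.21, the acyl-CoA dehydrogenase Acadm by 0.83 ± 0.18 and Cpt1a, the gate of mitochondrial fatty acid uptake, by 0.63 ± 0.16. Of 13 gluconeogenesis genes, 2 rose with p adjusted over the list alone, G6pc (1.57 ± 0.38), the glucose-6-phosphatase that releases glucose, and Sds (0.68 ± 0.15), serine dehydratase (camera adjusted p = 0.00707; adjusted p = 0.295 with an estimated correlation). Pck1, which makes phosphoenolpyruvate, differed by 0.21 ± 0.13 and did not pass; it ranked 6 to 14 among probes in STZ and 19 to 25 in control, near the top of the scale. Of 18 oxidative stress genes, 7 rose and 0 fell with p adjusted over the list alone (camera adjusted p = 3.08e-05; adjusted p = 0.295 with an estimated correlation). The metallothioneins Mt2 and Mt1, which bind zinc and copper, were 23.6-fold and 4.03-fold higher (4.56 ± 0.42 and 2.01 ± 0.23), and Nfe2l2, a regulator of antioxidant genes, differed by 1.22 ± 0.13. The count that passed over all genes tested was 0 in each of these lists.

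Of 20 cell cycle genes, 1 rose with p adjusted over the list alone, Cdkn1a (4.42 ± 0.58), an inhibitor of cyclin-dependent kinases that holds the cycle back. The replication licensing genes Mcm3 (2.28 ± 0.60) and Mcm5 (2.41 ± 0.80) did not pass. The list was called higher (camera adjusted p = 0.00108; adjusted p = 0.542 with an estimated correlation). Of 17 interferon response genes, 4 rose with p adjusted over the list alone, among them Irf1 (2.50 ± 0.64), a transcription factor, and Mx1 (1.67 ± 0.36), an antiviral GTPase. That list had camera adjusted p = 0.00138, and adjusted p = 0.542 with an estimated correlation. Without control sample 1 its camera adjusted p was 0.165. Of 15 immediate early genes, 4 rose with p adjusted over the list alone, among them the transcription factors Junb (1.66 ± 0.14) and Egr1 (2.70 ± 0.49), at camera adjusted p = 0.00697 and adjusted p = 0.295 with an estimated correlation. Of the members of these lists, 0 passed over all genes tested.

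Markers of cholangiocytes, the cells that line bile ducts, were higher in STZ: 3 of 9 rose with p adjusted over the list alone, Krt19 (1.25 ± 0.24), Tspan8 (1.47 ± 0.28) and Anxa13 (1.69 ± 0.34). Camera gave adjusted p = 0.00469, and adjusted p = 0.295 with an estimated correlation. Of 9 genes with higher expression in female than male liver, 4 rose with p adjusted over the list alone, led by A1bg (2.47 ± 0.37). Acot3 (1.79 ± 0.50) is 1 of these 4 and also belongs to the fatty acid oxidation list. Camera gave adjusted p = 0.00468, and adjusted p = 0.387 with an estimated correlation. Of 8 male-biased genes, 2 fell with p adjusted over the list alone, Nudt7 (-1.30 ± 0.21) and C8b (-0.88 ± 0.14), at camera adjusted p = 0.00707 and adjusted p = 0.295 with an estimated correlation. The female-biased call ended without control sample 1 (adjusted p = 0.0883) and the male-biased call without STZ sample 2 (adjusted p = 0.0652). The sex-biased calls rest on part of each list, since 9 of 23 fixed female-biased genes and 8 of 21 fixed male-biased genes were measured. For these marker and sex-biased lists, 0 members passed over all genes tested. Erythroid markers had a mean log2 difference of -0.83 over 5 genes and were not called by camera (adjusted p = 0.151). Of the 11 lists camera called, fry called 6 and not fatty acid synthesis (adjusted p = 0.194), cell cycle (0.248), interferon (0.4), female-biased (0.0866) or cholangiocyte genes (0.059).

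Over all genes, limma called 1 gene, Top2b (DNA topoisomerase II beta), at 3.24 ± 0.15 and adjusted p = 0.0081. Its log2 values were 5.64 on the first array of both controls, where intensities were -7.06 and -11.33, and 12.20 and 11.92 on their second arrays, against 11.73 to 12.39 on the 8 arrays of the other groups. Without the genes whose arrays differed by over 3 on the log2 scale, 0 genes were called. The 7 further named genes that were higher, with adjusted p of 0.064 or 0.065, did not pass. They were Id1 (2.99 ± 0.24) and Id3 (1.85 ± 0.14), inhibitors of helix-loop-helix factors, Junb, Acot1, Mt2, Tubb2a (2.23 ± 0.22), a beta-tubulin, and Frmd5 (2.81 ± 0.30). The 8 that were lower did not pass either. These were Rsph9 (-2.95 ± 0.26), a cilium component, Hhex (-1.89 ± 0.18), a homeobox factor of liver development, Slc39a4 (-1.41 ± 0.15), a zinc importer, Atad3aos (-1.53 ± 0.15), Rps23rg1 (-1.65 ± 0.17), Capn8 (-1.39 ± 0.15), Nsdhl (-1.67 ± 0.18), a sterol dehydrogenase, and Mvd. Of the other panel genes, Igfbp1 (0.83 ± 0.67), Irs2 (-0.28 ± 0.25), Fgf21 (-0.29 ± 0.20), Pdk4 (-0.07 ± 0.19), Pklr (-0.05 ± 0.21) and Srebf1 (0.33 ± 0.21) did not pass.

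At an unadjusted p under 0.05 stood 3010 genes, 1504 higher and 1506 lower, where 887 would arise by chance. At 2-fold or more, 315 of these were higher and 167 lower. The samples of STZ and control did not overlap for 52.1% of genes, where chance gives 33.3%. The adjusted count of 1 became 0 without control sample 1, STZ sample 1 or STZ sample 2, 3 without control sample 2 and 185 without either STZ+MENS sample, and the unadjusted count of 3010 became 1811 without control sample 2, 1941 without STZ sample 1 and 1953 without STZ sample 2. With either STZ+MENS sample left out, the remaining one adds nothing to the spread, so that setting amounts to a fit of STZ and control alone. In the fit of STZ and control alone, 185 genes were called over all genes, 103 higher and 82 lower. They held 25 members of the lists and 18 of the genes named for this comparison, which are the 16 taken by p together with Scd1 and Fasn. Among them were Cdkn1a (adjusted p = 0.008 in that fit), Mvd and Acot1 (both 0.014), Mt2 (0.021), Scd1 (0.044) and Mcm5 (0.047). The statements above that these genes did not pass, and the counts of 0 list members, hold for the fit of all 3 groups.

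**Figure D2:**
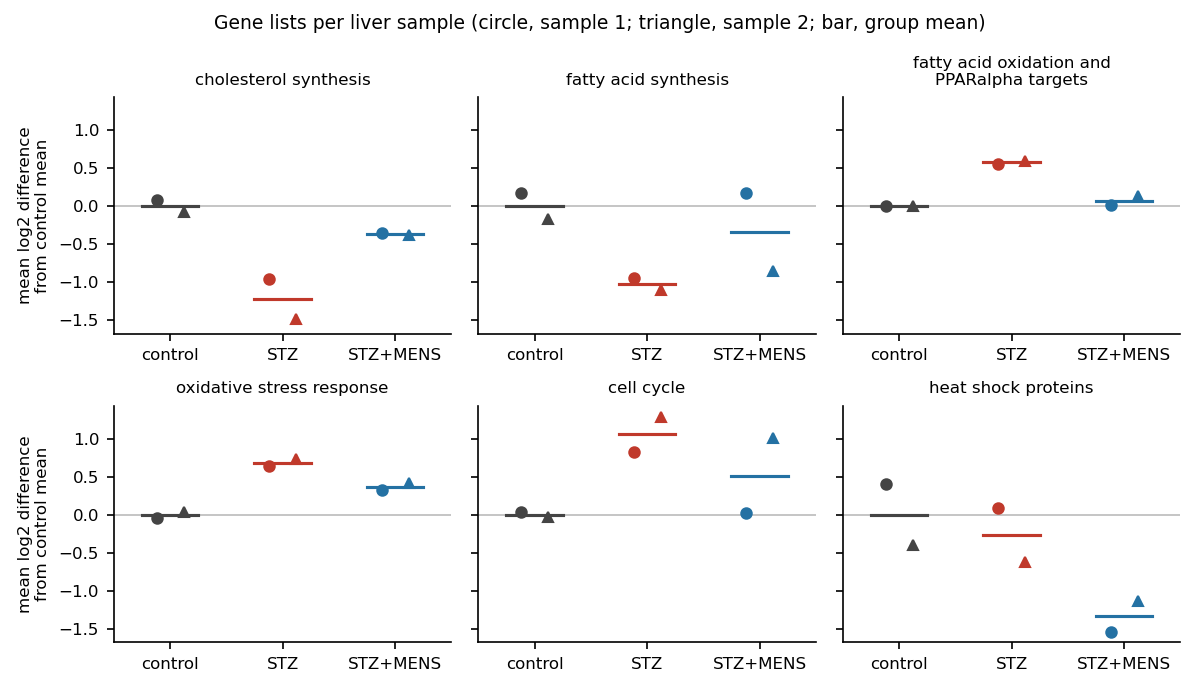
Mean log2 difference from the control mean of the members of gene lists, with circles for sample 1, triangles for sample 2 and bars for group means. Cholesterol synthesis stood at -0.96 and -1.49 in STZ and at -0.35 and -0.38 in STZ+MENS, while fatty acid synthesis stood at 0.17 in STZ+MENS sample 1 and -0.85 in sample 2.

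The second comparison asked how MENS-treated STZ mice differed from untreated STZ mice. Cholesterol synthesis genes were higher after MENS: 10 of 16 rose and 0 fell with p adjusted over the list alone, and 0 passed over all genes tested. Mvd was 7.05-fold higher (2.82 ± 0.33), with a mean of 13.67 ± 0.63 (SD) against 10.85 ± 0.26 in STZ. Mvk, mevalonate kinase, differed by 1.33 ± 0.15, Insig1 by 1.30 ± 0.20 and Fdft1, squalene synthase, by 1.22 ± 0.16. The camera adjusted p was 4.36e-05, and adjusted p = 0.699 with an estimated correlation. Fry did not call the list (adjusted p = 0.0886). The list means of both STZ+MENS samples, -0.35 and -0.38 relative to control, lay above those of both STZ samples, -0.96 and -1.49.

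Fatty acid oxidation and PPARalpha target genes were lower after MENS: 8 of 20 fell and 0 rose with p adjusted over the list alone (camera adjusted p = 0.00291; adjusted p = 0.699 with an estimated correlation). Ehhadh, a peroxisomal oxidation enzyme, was 4.41-fold lower (-2.14 ± 0.23), Acot2 differed by -1.19 ± 0.21, Acadm by -0.89 ± 0.18 and Plin2, a lipid droplet coat protein, by -1.63 ± 0.43. Of 18 oxidative stress genes, 6 fell and 2 rose with p adjusted over the list alone (camera adjusted p = 0.0123; adjusted p = 0.699 with an estimated correlation). Nfe2l2 differed by -0.85 ± 0.13, Txnrd1, a thioredoxin reductase, by -1.06 ± 0.17 and Mt1 by 0.98 ± 0.23, while Mt2 (-0.10 ± 0.42) did not pass. Of 11 heat shock genes, 3 fell with p adjusted over the list alone, the chaperones Dnaja1 (-1.26 ± 0.23), Hspa4l (-1.36 ± 0.32) and Hspe1 (-2.11 ± 0.54), at camera adjusted p = 0.00187 and adjusted p = 0.699 with an estimated correlation. The STZ samples themselves stood apart in the heat shock list, at 0.09 and -0.62 from the control mean, against -1.54 and -1.13 in STZ+MENS. Over all genes tested, 0 members of these lists passed. The oxidative stress call ended without STZ sample 2 (adjusted p = 0.0766).

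Fatty acid synthesis genes were higher after MENS by camera (adjusted p = 0.0348; adjusted p = 0.857 with an estimated correlation). Of 16, 3 rose with p adjusted over the list alone, Thrsp (1.74 ± 0.35), Acaca (1.05 ± 0.22) and Mlxipl (0.95 ± 0.22), a carbohydrate-responsive factor. Scd1 (1.68 ± 0.76) and Fasn (1.56 ± 0.72) did not pass. The STZ+MENS samples differed, with Scd1 at 18.88 in sample 1 and 16.58 in sample 2 against 16.70 and 15.40 in STZ, and on 1 array of sample 1 it was the brightest probe. The call ended without STZ+MENS sample 1 (mean log2 0.17, adjusted p = 0.421), without STZ sample 2 (adjusted p = 0.11) and at an offset of 200 (adjusted p = 0.0569). Erythroid markers split the same samples, with mean log2 0.18 and -1.38 from control in STZ+MENS samples 1 and 2. Of 16 respiratory chain genes, 3 fell with p adjusted over the list alone, Atp5b (-0.99 ± 0.14), Sdha (-1.20 ± 0.28) and Cox5a (-1.53 ± 0.38), at camera adjusted p = 0.0348 and adjusted p = 0.857 with an estimated correlation. That call ended without STZ sample 1 (adjusted p = 0.247) or STZ+MENS sample 1 (adjusted p = 0.154). Of the 6 lists camera called, fry called 1, fatty acid oxidation (adjusted p = 0.0433), and not oxidative stress (0.0648), heat shock (0.233), fatty acid synthesis (0.313), respiratory chain (0.304) or cholesterol synthesis. Over all genes tested, 0 members of these lists passed.

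Over all genes limma called 0, with a lowest adjusted p of 0.0569, and 4503 genes had an unadjusted p under 0.05, 2243 higher and 2260 lower, where 887 would arise by chance. At 2-fold or more, 183 of these were higher and 622 lower. The samples of the groups did not overlap for 57.9% of genes, where chance gives 33.3%. The named genes that were lower, all without passing at adjusted p = 0.057, were Nkain2 (-2.15 ± 0.16), Tubb2a (-2.24 ± 0.22), Tmem267 (-2.13 ± 0.21), Nt5dc1 (-1.65 ± 0.16), Tmem18 (-1.60 ± 0.15), Smim15 (-1.50 ± 0.14), Txnl1 (-1.41 ± 0.13), a thioredoxin-like protein, and Ttpa (-1.41 ± 0.14), the vitamin E transfer protein. Those that were higher at the same adjusted p were Mvd, Mvk, Serpina5 (1.88 ± 0.23), a protease inhibitor, Atad3aos (1.48 ± 0.15), Isoc2a (1.32 ± 0.14), B3galt1 (1.28 ± 0.14), Ccdc167 (1.18 ± 0.14) and Zfp653 (1.15 ± 0.14). G6pc was 4.74-fold lower after MENS (-2.25 ± 0.38, adjusted p = 0.059) and missed the threshold over all genes. With p adjusted over the list alone, it was 1 of 4 of the 13 gluconeogenesis genes that fell, with Tat (-1.17 ± 0.23), Got1 (-0.98 ± 0.23) and Creb3l3 (-0.47 ± 0.15), while Pcx (0.59 ± 0.14), pyruvate carboxylase, rose. In that list 0 passed over all genes tested, and camera did not call it (adjusted p = 0.251). Cpt1a (-0.19 ± 0.16), Fgf21 (0.52 ± 0.20), Igfbp1 (-0.60 ± 0.67), Irs2 (0.16 ± 0.25), Pck1 (-0.16 ± 0.13), Pdk4 (-0.20 ± 0.19), Pklr (0.50 ± 0.21) and Srebf1 (-0.31 ± 0.21) did not pass. The adjusted count was 1764 without STZ+MENS sample 2 and 1 without STZ+MENS sample 1, and the unadjusted count was 2394 without STZ sample 1.

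**Figure D3:**
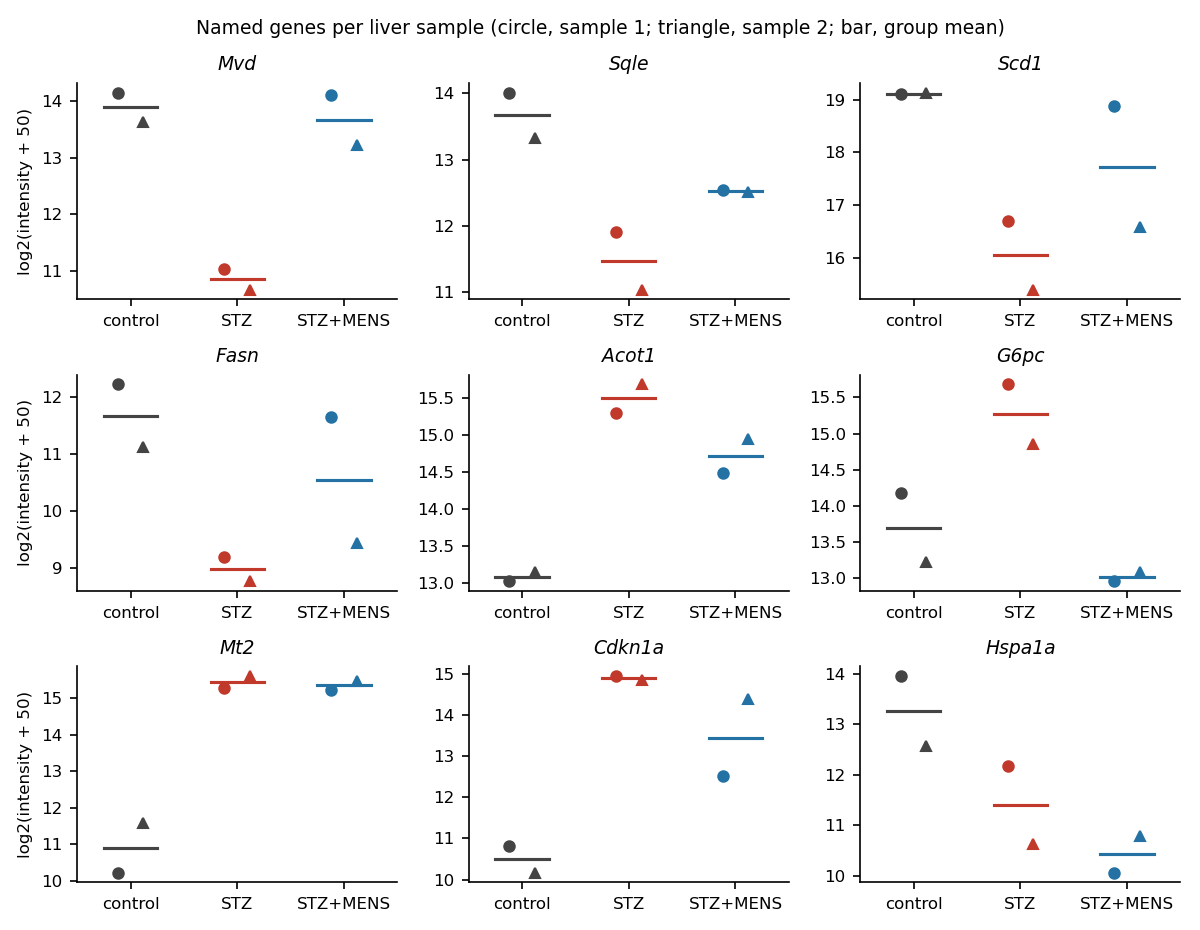
Log2 intensity of selected genes in each of the 6 samples, with circles for sample 1, triangles for sample 2 and bars for group means. Mt2 lay at 15.23 and 15.48 in STZ+MENS against 10.22 and 11.57 in control, and Scd1 lay at 18.88 and 16.58 in STZ+MENS against 19.10 and 19.13 in control.

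The third comparison asked how MENS-treated STZ livers differed from control livers. Heat shock genes were lower: 9 of 11 fell and 1, Hspb1 (0.95 ± 0.17), rose with p adjusted over the list alone, and 0 passed over all genes tested. Hspa1a, the inducible Hsp70 chaperone, was 7.15-fold lower (-2.84 ± 0.64), at 13.26 ± 0.98 (SD) in control and 10.43 ± 0.52 in STZ+MENS. Its cochaperones Dnajb1 and Bag3 differed by -2.21 ± 0.51 and -1.52 ± 0.38. Camera gave adjusted p = 0.000207, and adjusted p = 0.884 with an estimated correlation. The control samples themselves stood apart in this list, with means of 0.40 and -0.40 around their average, against -1.54 and -1.13 in STZ+MENS. Interferon response genes were called higher (camera adjusted p = 0.04; adjusted p = 0.884 with an estimated correlation). Of 17 members 0 passed with p adjusted over the list alone and 0 over all genes tested, and Mx1 (1.67 ± 0.36) and Irf1 (2.55 ± 0.64) led. That call ended without control sample 1 (adjusted p = 0.381) and without STZ+MENS sample 2 (adjusted p = 0.93), without the dimmest 25% of probes (adjusted p = 0.0585) and at an offset of 200 (adjusted p = 0.0742). Fry called neither list (adjusted p = 0.305 for heat shock and 0.551 for interferon).

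Mt1 and Mt2 were 7.97-fold and 22-fold higher than control (2.99 ± 0.23 and 4.46 ± 0.42). These were 2 of the 18 oxidative stress genes and rose with p adjusted over the list alone, 0 passed over all genes tested, and the list was not called by camera (adjusted p = 0.787). Cholesterol synthesis genes had a median of -0.35 and were not called by camera (adjusted p = 0.118), nor were fatty acid oxidation genes (median 0.01, adjusted p = 0.787). With p adjusted over the list alone, 0 cholesterol synthesis genes passed. Of the 20 oxidation genes, Acot1 rose and Ehhadh fell in this way. Of 18 ER stress and amino acid response genes 5 fell and 1 rose, and of 13 gluconeogenesis genes 3 rose and 1 fell. Camera called neither of these 2 lists (adjusted p = 0.0947 and 0.852). Scd1 (-1.39 ± 0.76), Fasn (-1.13 ± 0.72), G6pc (-0.68 ± 0.38) and Cpt1a (0.44 ± 0.16) did not pass, nor did Fgf21 (0.24 ± 0.20), Igfbp1 (0.23 ± 0.67), Irs2 (-0.12 ± 0.25), Pck1 (0.04 ± 0.13), Pdk4 (-0.27 ± 0.19), Pklr (0.45 ± 0.21) and Srebf1 (0.01 ± 0.21).

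Over all genes limma called 1, Top2b (3.21 ± 0.15, adjusted p = 0.0086), with the array values given above, and 0 without the genes whose arrays differed by over 3 on the log2 scale. An unadjusted p under 0.05 was found for 3196 genes, 1567 higher and 1629 lower, where 887 would arise by chance. At 2-fold or more, 179 of these were higher and 333 lower. The named genes that were higher without passing were Mt1, Mt2, Lgals2 (1.52 ± 0.16), a galectin, Olfr1413 (1.37 ± 0.15), CEP110 (1.35 ± 0.16), Ifnlr1 (1.19 ± 0.14), a receptor of lambda interferons, and Junb (1.13 ± 0.14). Those that were lower without passing were Rsph9 (-2.68 ± 0.26), Sucnr1 (-2.04 ± 0.23), the succinate receptor, Ugcg (-1.32 ± 0.15), glucosylceramide synthase, Zfp36l3 (-1.28 ± 0.14), Avpr1a (-1.20 ± 0.13), a vasopressin receptor, Slain2 (-1.17 ± 0.14), Rpgr (-1.17 ± 0.14) and Trp53inp2 (-1.12 ± 0.14). The adjusted count of 1 was 0 without control sample 1, 3 without control sample 2, 2 without either STZ sample or STZ+MENS sample 1, and 12 without STZ+MENS sample 2. The unadjusted count was 1799 without control sample 1.

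Across genes, the STZ difference from control and the MENS difference from STZ ran opposite, with r = -0.569 and a covariance of -0.12. Both use the STZ samples, and unchanged groups simulated with that sharing gave r = -0.499 (-0.524 to -0.469) and a covariance of -0.0273, so the observed covariance differed from it by -0.0927. With no sample in common the covariance was -0.0876. Genes are not independent replicates, but the simulations drew them as independent, so simulated ranges are too narrow where genes vary together. At an unadjusted p under 0.05, 689 genes were higher in STZ than in control and lower in STZ+MENS than in STZ (simulated 107, independent lists 192). In the opposite directions there were 778 (simulated 106, independent lists 190). The groups are different samples, so no gene was followed over time. Against control, 412 genes were higher in both STZ and STZ+MENS (simulated 109, independent lists 133) and 315 lower in both (simulated 107, independent lists 138). The differences of STZ and STZ+MENS from control had r = 0.353 (simulated 0.498) and a covariance of 0.0654 (simulated 0.0272), so r lay below and the covariance above the simulated value, and part of the excess counts may come from the shared samples. Called in both was 1 gene, Top2b (simulated 0.02, independent lists 5.6e-05). Both calls rest on the same first control arrays with intensities below 0, which neither value models, so these values do not gauge the overlap. This overlap was 0 without control sample 1 or either STZ sample, 3 without control sample 2, 2 without STZ+MENS sample 1 and 5 without STZ+MENS sample 2.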

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

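The offsets of 16 and 200 and the removal of genes with discordant arrays were chosen after seeing the data. The main offset of 50 was not part of the plan either. The other settings here were planned. With 2 samples per group, leaving a sample out leaves 1 in its group, which is then assumed to vary like the other groups. Where that group is not one of those compared, the fit is the same as with only the compared groups. At an adjusted p under 0.05 the count for STZ against control was 1. It was 81 with array weights, 185 with only the compared groups, 4 on first arrays, 0 on second arrays, 0 at an offset of 200, 0 without discordant genes, 1642 at unadjusted p under 0.05 with 1.5-fold, 116 at an adjusted p under 0.1 and 0 to 185 with a sample left out. For STZ+MENS against STZ it was 0, and it was 30 on second arrays, 2729 at unadjusted p with 1.5-fold, 1744 at an adjusted p under 0.1 and 0 to 1764 with a sample left out. For STZ+MENS against control it was 1, and it was 2 with only the compared groups, 3 on first arrays, 0 on second arrays, 0 at an offset of 200, 0 without discordant genes, 1929 at unadjusted p with 1.5-fold, 2 at an adjusted p under 0.1 and 0 to 12 with a sample left out. In the same order, 12 arrays with the sample as a random block gave 1203, 3071 and 1328 genes. That fit used 1 correlation of 0.485 between the arrays of a sample for all genes. Genes that vary more between samples are then tested with too small an error, so these are not counts for n = 2. The 12 arrays taken as independent gave 3193, 5581 and 3446, because arrays of a sample then count as replicates. Unadjusted counts became 5681, 7426 and 5854 on independent arrays, and ranged from 1811 to 3506, 2394 to 5171 and 1799 to 3717 with a sample left out. Normalization, dim probes, the choice of probe, the intensity trend and an offset of 16 kept every count of genes within 1.5 times.

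Sample numbers did not pair the samples (correlations of deviations 0.006, -0.031 and -0.07), and the replicate block by sample number gave 1, 0 and 1 genes. Array numbers correlated at -0.228 to 0.344 over 15 pairs, 4 of them over 0.1. The replicate block by array number on 12 arrays gave 1023, 2731 and 1049, with the same limit as the random-block fit above.

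Of 11, 6 and 2 list calls, an estimated correlation left 0 in each comparison. In STZ against control this included called lists whose estimate was below the preset 0.01. These were fatty acid oxidation (0.001), gluconeogenesis (-0.071), male-biased (-0.023) and cholangiocyte genes (-0.004), so a higher correlation does not account for their loss. With an estimated correlation camera uses only the 3 residual degrees of freedom, which raises p whatever the estimate. The p-values with an estimated correlation are thus not a correction for correlation alone. The other called lists there had estimates of 0.017 to 0.463. For fatty acid oxidation, camera's unadjusted p went from 4.31e-06 to 0.0157. Fry gave 8 for STZ against control, 6 of them also called by camera, 2 for STZ+MENS against STZ, 1 of them also called by camera, and 0 for STZ+MENS against control, so 12 of the 19 camera calls were lost. The last comparison had 1 call without dim probes and 1 at an offset of 200. With a sample left out the ranges were 9 to 15, 4 to 10 and 1 to 7. No called list changed direction under any setting. The overlap of calls ranged from 0 to 5 with a sample left out, and the covariance of the STZ and MENS differences from -0.17 to -0.0877. Of 1940 gene results under other settings, 1667 kept direction and side of the threshold, 243 newly passed, 16 lost the threshold (all Top2b) and 14 turned sign, in 8 gene comparisons of which 0 passed the threshold. Pck1 in STZ+MENS against control was -0.08 on second arrays, and Srebf1 there was -0.11 on first arrays. With a sample left out, Srebf1 ranged from -0.14 to 0.17, Igfbp1 from -0.65 to 1.11 and Irs2 from -0.35 to 0.11 in that comparison. Igfbp1 ranged from -1.48 to 0.28, Irs2 from -0.07 to 0.39 and Pdk4 from -0.44 to 0.03 in STZ+MENS against STZ, and Pklr from -0.21 to 0.11 in STZ against control. Except where stated, the cause was not tested. The 652 genes with a mean intensity under the offset of 50 have differences compressed toward 0.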

Other observations

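The tests of explanations for Top2b, for the opposite differences and for the places of the STZ+MENS samples were chosen only after the result was seen, although the fit on second arrays was planned as a setting, as were the list tests. Genes of glycogen metabolism were not described above. In STZ against control, 3 of 6 rose with p adjusted over the list alone: Ppp1r3c (1.33 ± 0.25 SE, n = 2 per group), a subunit that directs phosphatase to glycogen, Ugp2 (0.65 ± 0.22), which makes UDP-glucose, and Gbe1 (0.56 ± 0.15), the branching enzyme. Of the 6, 4 were higher in STZ and 2 lower. Ppp1r3g did not pass and was lower, at 13.64 and 12.23 in the control samples and 12.09 and 10.80 in the STZ samples. In STZ+MENS against STZ, 4 of 6 fell with p adjusted over the list alone, among them Ppp1r3c (-1.31 ± 0.25) and Gbe1 (-1.17 ± 0.15), and 1, Phka2 (1.07 ± 0.17), a phosphorylase kinase subunit, rose. Over all genes tested 0 passed, and neither camera (adjusted p = 0.0914 and 0.173) nor fry (adjusted p = 0.199 and 0.233) called the list. Cidec, a lipid droplet protein, was 1 of 2 adipocyte markers that rose with p adjusted over the list alone in STZ (1.38 ± 0.21), beside Fabp4 (1.43 ± 0.31), and fell over the list alone after MENS (-0.98 ± 0.21). Over all genes tested 0 of these 9 markers passed, and camera did not call the list (adjusted p = 0.0596 and 0.261), while fry did (adjusted p = 0.0248 and 0.0433). Fry also called pancreatic acinar markers in STZ against control (adjusted p = 0.0248) and camera did not (adjusted p = 0.245). Of these 12 markers 9 were lower, the median difference was -0.13, and 1, Cela1 (-1.13 ± 0.22), an elastase, fell with p adjusted over the list alone, with 0 passing over all genes tested.

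The Top2b call against control may be a failed spot on the first control arrays of both samples, where the intensity was below 0. With second arrays only, the log2 difference of STZ from control was 0.01, and the lower of the differences of STZ and STZ+MENS from control was 0.01, which argues against a higher Top2b level in the STZ-treated groups. Top2b was 1 of 72 genes with arrays of a sample over 3 apart on the log2 scale, and 37 such genes lay in control sample 2. What made the spots dim stays open.

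The opposite signs of the STZ and MENS differences may, as a hypothesis, come from genes moved by STZ and moved back in the treated mice. No group shows the treated mice before MENS, so a move back was not observed as such. With no sample in common the covariance was -0.0876, so it stayed negative without shared STZ samples. Simulated unchanged groups gave -0.0024 to 0.0026, but each gene was drawn independently there. Deviations shared by many genes would widen that range, so with 6 samples it cannot exclude chance. The negative sign did not rest on a single STZ+MENS sample, since with each left out in turn the weaker covariance was -0.0553. A handling difference of the STZ samples as a set cannot be told apart from a treatment effect. The covariance of the STZ and STZ+MENS differences from control, with no control in common, was 0.0322. An STZ difference partly kept in STZ+MENS would give that sign. A handling difference of the control samples as a set would give it too, because using different controls does not remove what they share. The covariance cannot tell these apart. Because each gene was drawn independently, the simulations cannot exclude chance either.

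Over the 3010 genes at unadjusted p under 0.05 for STZ, STZ+MENS sample 1 kept 23.8% of the STZ shift and sample 2 kept 56.3%, so a control liver labelled as sample 1 might be considered. Over all genes neither sample lay between control and STZ on the first principal component (50.2 and 13.1, against -3.6 and 4.3 in control and -38.9 and -25 in STZ), and sample 1 correlated with the controls at 0.976 and 0.98, against 0.99 between the controls. On genes chosen without a held-out control, that control itself lay at 26.5% or 27.2% and sample 1 at 29% or 37.6%, which does not separate them. Over genes shifted from control in both STZ and STZ+MENS sample 2, however, sample 1 lay further out than the held-out control by 24.6 or 20.9 percentage points. This argues against a control liver handled together with the 2 control samples. These genes would also carry any handling difference of the controls as a set. The gap thus cannot exclude a control liver handled with the STZ+MENS samples. A difference in response between the samples stays open as a hypothesis, untested with 2 samples.

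The gene lists did not all split the STZ+MENS samples. Cell cycle genes kept 2% of the STZ shift in sample 1 and 95% in sample 2, fatty acid synthesis genes -17% and 83%, interferon genes 26% and 136%, and female-biased genes 28% and 69%. The controls themselves lay at 0.03 and -0.03 for cell cycle and -0.23 and 0.23 for interferon genes. They lay at 0.17 and -0.17 for fatty acid synthesis and -0.12 and 0.12 for female-biased genes. The STZ means, in that order, were 1.06, 0.86, -1.02 and 0.78. For cell cycle (0.02), interferon (0.22) and fatty acid synthesis (0.17), sample 1 thus lay no further from the control mean than a single control. Cholesterol synthesis genes kept 29% and 31%, immediate early genes 35% and 46%, and male-biased genes 31% and 21%. Gluconeogenesis genes kept -30% and 10%, about as far apart as the female-biased genes. No rule or test divided lists that split the samples from those that did not. Markers of other cell types differed between the samples as well, with mean log2 differences from control of 0.18 and -1.38 for erythroid markers (controls 0.11 and -0.11) and -0.32 and 0.32 for Kupffer cell and macrophage markers (controls 0.17 and -0.17).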
